A study of Mus musculus with 24 samples.

How the data were processed

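RNA was sequenced from MOVAS cells, a mouse aortic smooth-muscle cell line, in 24 libraries of 8 groups with 3 libraries each. The groups came from 4 backgrounds, WT, ADAM9i (given an ADAM9 inhibitor), Rosa26-KO and Adam9-KO, each with vehicle or rhCTHRC1 (recombinant human CTHRC1). Libraries were made with a TruSeq stranded total RNA kit and read as 150-base paired ends. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the genome build GRCm38, without versions. Aligner settings, the annotation, the use of strand in counting, and whether a count is a read or a read pair are not given in the sources used here.

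The deposited table holds, for 33034 genes, a raw count per gene and library made by the authors, with replicates kept apart. It also holds FPKM values, which the authors computed as fragments per kilobase scaled to the number mapped. Gene positions and identifiers are those of the deposited table. Some symbols, 124 entries in all, are shared with another entry. The counts were used for all main results, and FPKM for 1 alternative.

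Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, and version 1.17.8 of data.table). WT and ADAM9i, here called the inhibitor experiment, and Rosa26-KO and Adam9-KO, here called the knockout experiment, were fitted apart. Each fit held 12 libraries, which leaves 8 residual degrees of freedom. This grouping was made here, and the sample titles name no experiments. Titles of the WT libraries follow another pattern than those of the other backgrounds. Between WT and ADAM9i, too, a difference in handling can therefore not be told apart from the background. The comparisons between the experiments used all 24 libraries, and in these a difference of experiment and a difference of background cannot be told apart. Genes were kept by filterByExpr, which left 18816 genes in the inhibitor experiment, 18594 in the knockout experiment and 19891 over all libraries. Libraries were scaled by TMM. A group-means model was fitted with robust quasi-likelihood dispersions and tested two-sided by the quasi-likelihood F test, and p was adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The adjusted p in the text are from edgeR unless camera, DESeq2 or limma is named. The 10 comparisons were the response to rhCTHRC1 in each of 4 backgrounds, 3 differences of responses and 3 differences under vehicle. Levels are TMM-scaled CPM. Correlations were taken across genes, which are not independent replicates. Principal components used log2 CPM with a prior count of 2, and figures were drawn with matplotlib 3.10.9.

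The comparisons, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. The 27 gene lists hold 653 members, of which 643 have an entry. They cover contractile and modulated smooth muscle, collagens and matrix structure, matrix proteases and inhibitors, the ADAM family, inflammatory cytokines and NF-kB targets, the interferon response, Wnt, TGF-beta and BMP targets, YAP and SRF targets, immediate early and ERK feedback genes, the cell cycle, cholesterol synthesis, the unfolded protein and ATF4 response, hypoxia and glycolysis, p53 targets, NRF2 targets, Notch targets, osteochondrogenic markers, EGFR ligands and receptors, integrins, mitochondrially encoded genes, cytosolic ribosomal proteins, and endothelial, macrophage, fibroblast and epithelial markers. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were counted over all genes and adjusted over the list alone.

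The rule named Adam9 and Cthrc1, the 6 largest rises and the 6 largest falls among called genes with at least 1 CPM and no overlap of libraries, up to 3 called members of each list that passed or had at least 3 calls, the 4 genes of smallest p where fewer than 4 were called, and Acta2, Tagln, Myh11, Cnn1, Il6, Ccl2, Mmp2 and Mmp9 in the 4 responses. It gave 622 entries of a gene in a comparison. The text draws on 177 of them, and which of these were named was picked after their values were seen. Some named by the rule are not reported here. Genes outside the rule were also chosen after their values were seen: Hspa5, Chac1, Col3a1, Nsdhl and Acta2 between Rosa26-KO and WT vehicle, Hspa5, Fdps, Col3a1, Irf7, Acta2, Egr1 and Fos in the Rosa26-KO minus WT response, the levels given for WT vehicle, and the genes of the treated groups compared directly.

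Alternatives planned before were size factors by relative log expression (RLE), the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) with genes of FPKM at least 1 in at least 3 libraries, no filter on low counts, a fold of at least 2, other sets of libraries in the fit, the replicate number as a block, leaving out each library in turn, and an estimated correlation. Scaling by library size alone, and other vehicle libraries in place of WT vehicle, were chosen after seeing the data. Scaling by library size alone moved the median log2 change of all genes from 0.033 to 0.206 in the WT response, from 0.032 to 0.103 in the Rosa26-KO response, from -0.037 to -0.224 in the ADAM9i minus WT difference and from -0.022 to -0.104 in the Adam9-KO minus Rosa26-KO difference. The tests were tested on simulated data with the spread of these libraries, in which changed genes were drawn from those with a mean of at least 50 counts. With the spread of the Adam9-KO response, edgeR made 174 calls, 15 of them false, DESeq2 201 with 32 false, and limma 174 with 13 false. A limit of 3 counts was used for a count of 0. It covers counting error only.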

Results

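Gene expression was measured by RNA sequencing in MOVAS cells, a mouse aortic smooth-muscle cell line. The 24 libraries formed 8 groups of 3, from 4 cell backgrounds that each received vehicle or rhCTHRC1. rhCTHRC1 is recombinant human CTHRC1, a secreted protein named for its collagen-like triple-helix repeat. The backgrounds were unedited cells (WT), unedited cells given an inhibitor of ADAM9 (ADAM9i), cells edited at the Rosa26 locus (Rosa26-KO), a locus often edited as a control for the editing itself, and cells edited at Adam9 (Adam9-KO). ADAM9 is a membrane-anchored metalloprotease. The labels name neither the inhibitor nor any dose or time, and do not say whether the replicates of a group were separate cultures. Titles of the WT libraries also hold a C (vehicle) or a T (rhCTHRC1), which the other titles lack. Its meaning is not known here, and it changes together with the treatment. Each library held 53135752 to 65833125 counts in genes. A count of 0 in a library allowed a level of up to 0.045 to 0.058 CPM (counts scaled to a common library size), for counting error only. Levels below are CPM scaled by the trimmed mean of M values (TMM), as mean ± SD with n = 3, and log2 changes are given ± SE.

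The 3 WT vehicle libraries stood apart from all other libraries. On the first principal component, which held 24.9% of the variance, they lay between -119.3 and -114.5, and the other libraries between -7.2 and 54.3. Hspa5, the main chaperone of the endoplasmic reticulum, was at 2463 ± 82.4 CPM in WT vehicle and at 756 to 821 CPM in the other vehicle groups. Chac1, induced through ATF4, was at 421 ± 7.58 CPM there and at 30.8 to 65.1 CPM in the others. Col3a1, a fibrillar collagen, was at 6.12 CPM against 122 to 147 CPM. Nsdhl, an enzyme of cholesterol synthesis, was at 22.6 ± 1.99 CPM against 183 to 204 CPM. The proliferation marker Mki67 was at 175 ± 5.56 CPM against 578 to 624 CPM. The share of counts in mitochondrially encoded genes was 3.22% ± 0.01 in WT vehicle and 3.66% to 4.29% over the other groups' means. The counts of called genes and many of the lists and named genes that use the WT vehicle libraries are therefore also given with other vehicle libraries in their place, a choice made after the data were seen. Such values also hold any difference between the backgrounds and any effect of the inhibitor.

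**Figure D1:**
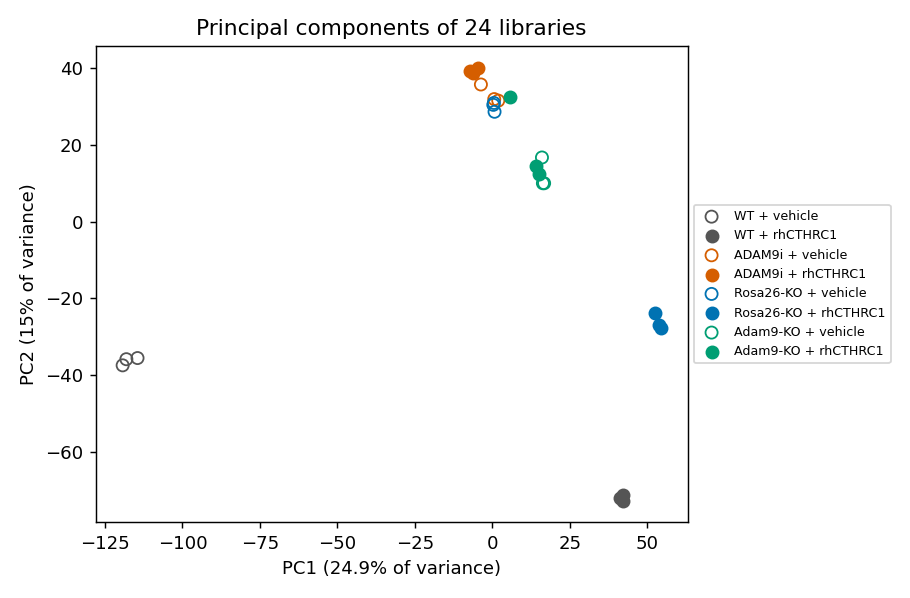
First and second principal components of log2 CPM for the 24 libraries, each point a library, coloured by group. The 3 WT vehicle libraries lie between -119.3 and -114.5 on the first component and all others between -7.2 and 54.3.

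Adam9 transcripts were lower, but not absent, in Adam9-KO cells. The gene lies on chromosome 8 from 24949611 to 25016927 (GRCm38, ENSMUSG00000031555). Under vehicle its level was 139 ± 10.1 CPM in Adam9-KO and 236 ± 6.35 CPM in Rosa26-KO cells, a log2 difference of -0.78 ± 0.05 (adjusted p = 3.59e-08). The 3 Adam9-KO vehicle libraries held 7468 to 9521 Adam9 counts each. Gene-level counts do not read the edit, so they do not show whether the remaining transcripts encode the protein. In ADAM9i cells under vehicle Adam9 was at 164 ± 6.48 CPM, against 249 ± 35.3 CPM in WT cells (log2 difference -0.61 ± 0.12, adjusted p = 0.00185). rhCTHRC1 raised Adam9 in Rosa26-KO cells, to 284 ± 9.79 CPM (log2 change 0.27 ± 0.05, adjusted p = 7.98e-05). The log2 change was 0.02 ± 0.05 in Adam9-KO cells (adjusted p = 0.952), and the difference of the responses was -0.24 ± 0.07 (adjusted p = 0.00572). It was 0.32 ± 0.12 in ADAM9i cells (adjusted p = 0.228) and 0.21 ± 0.12 in WT cells (adjusted p = 0.162). Treated WT cells were higher than the vehicle libraries of Rosa26-KO or of ADAM9i cells by 0.30 or 0.82, past the threshold. These 2 values also hold the difference of the backgrounds, and Adam9 was itself lower in ADAM9i than in WT vehicle. Under scaling by library size alone the change in WT cells passed at 0.39. Between WT and ADAM9i cells the responses of Adam9 differed by 0.12 ± 0.17 (adjusted p = 0.608). Cthrc1 itself had 0 counts in 23 of the 24 libraries and 3 counts in the other, so the cells' own transcript was not detectable at this depth. The added protein leaves no reads.

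**Figure D2:**
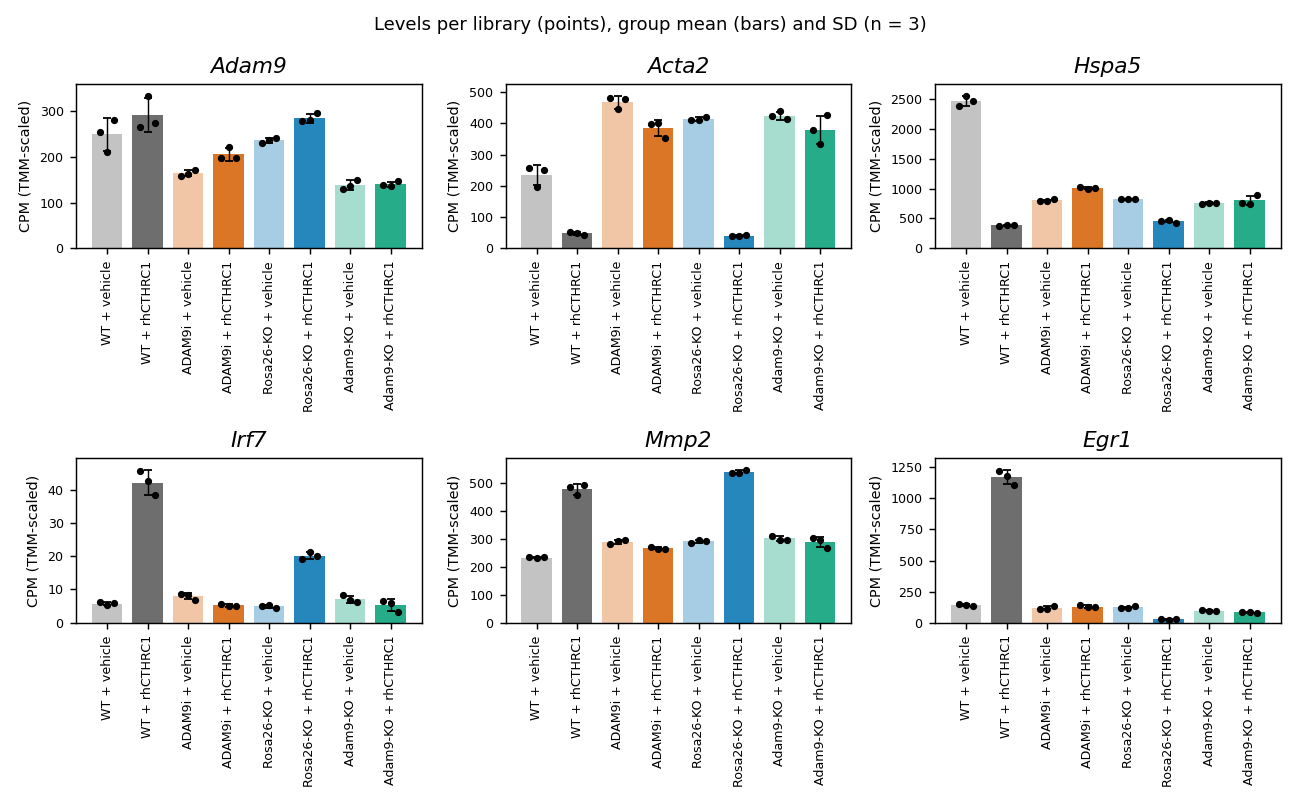
TMM-scaled CPM of Adam9, Acta2, Hspa5, Irf7, Mmp2 and Egr1 in the 8 groups. Bars are means, error bars are SD with n = 3 and points are libraries, and Adam9 is lowest in the Adam9-KO groups, at 139 and 140.2 CPM.

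In Rosa26-KO cells, the control for the editing, rhCTHRC1 lowered Acta2, Tagln and Myocd. Acta2, smooth-muscle actin, fell from 415 ± 5.72 to 40.6 ± 1.78 CPM (log2 change -3.35 ± 0.08, adjusted p = 7.41e-12; chromosome 19, 34241090 to 34255590, ENSMUSG00000035783). Tagln, an actin-binding protein of smooth muscle, fell by 1.44 on the log2 scale, and Myocd, the coactivator of smooth-muscle genes, by 1.80. Mmp2, a gelatinase, rose from 292 ± 4.99 to 539 ± 6.04 CPM (log2 change 0.89 ± 0.04, adjusted p = 2.06e-12). In all, 8413 of 18594 tested genes changed, 4087 higher and 4326 lower, and 1205 of them at least 2-fold. Scaling by library size alone gave 5084 higher and 3486 lower.

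Of the 35 interferon-response genes, 34 rose and 0 fell in Rosa26-KO cells, and 34 adjusted over the list alone (adjusted p = 1.43e-15 in camera, adjusted p = 0.15 with an estimated correlation). Zbp1, a sensor of nucleic acids, rose by 2.70 ± 0.41 on the log2 scale, and Ifit3b by 2.47 ± 0.25, although reads of Ifit3b cannot be told from those of its close paralog with certainty. Of the 30 genes of the unfolded protein and ATF4 response, 0 rose and 29 fell, and 29 adjusted over the list alone (adjusted p = 8.36e-19 in camera, adjusted p = 0.086 with an estimated correlation). Chac1 fell from 49.6 ± 2.71 to 10.4 ± 0.68 CPM, Trib3, a pseudokinase induced by ATF4, by 2.12 on the log2 scale, and Mthfd2, of mitochondrial folate metabolism, by 1.87. Of the 38 cell-cycle genes, 1 rose and 32 fell, and 1 and 34 adjusted over the list alone (adjusted p = 1.07e-09 in camera, adjusted p = 0.151 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 0.68, the checkpoint kinase Bub1 by 0.57, and Ccna2, cyclin A2, by 0.53. Of the 25 genes of cholesterol synthesis, 19 rose and 0 fell, and 19 adjusted over the list alone (adjusted p = 5.45e-08 in camera, adjusted p = 0.273 with an estimated correlation). Tm7sf2, a sterol reductase, rose by 1.72 ± 0.08, and Insig1, which restrains sterol synthesis, by 1.19 ± 0.03.

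Further lists passed the threshold in camera in Rosa26-KO cells, and 0 of them held with an estimated correlation. Of 29 tested immediate early genes and feedback genes of ERK, 5 rose and 17 fell, and 5 and 18 adjusted over the list alone (adjusted p = 0.00016 in camera, adjusted p = 0.127 with an estimated correlation). Egr1, a growth-factor-induced transcription factor, fell from 124 ± 6.03 to 27.04 ± 1.46 CPM, Fosl1, a component of AP-1, by 2.33 on the log2 scale and Atf3 by 2.04. Of 28 genes of hypoxia and glycolysis, 4 rose and 18 fell, and the same numbers adjusted over the list alone (4 and 18; adjusted p = 0.00016 in camera, adjusted p = 0.197 with an estimated correlation). Ldha, lactate dehydrogenase, fell from 782 ± 31.8 to 333 ± 6.59 CPM, and the glycolytic enzymes Pgk1 and Hk2 fell by 0.93 and 0.92. Of 25 p53 targets 3 rose and 14 fell, with 3 and 15 adjusted over the list alone (adjusted p = 0.0082 in camera, adjusted p = 0.123 with an estimated correlation), among them Gdf15 with -1.61 ± 0.16 and Sesn2 with -1.39 ± 0.11. Of 22 targets of YAP and SRF 5 rose and 12 fell, the same numbers (5 and 12) adjusted over the list alone (adjusted p = 0.0262 in camera, adjusted p = 0.618 with an estimated correlation). Ankrd1 and Ccn2, both classic YAP targets, fell by 1.31 and 1.55. Of 14 fibroblast markers 9 rose and 1 fell, and 9 and 1 adjusted over the list alone (adjusted p = 0.0174 in camera, adjusted p = 0.151 with an estimated correlation), among them Col14a1 with 1.81 ± 0.17 and Dpt with 2.39 ± 0.34.

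Other lists moved in both directions or missed the threshold in Rosa26-KO cells. Contractile smooth-muscle genes split into 9 higher and 9 lower of 24 (9 and 9 adjusted over the list alone). Their median was 0.16 and their mean -0.11, so the list has no common direction. Modulated smooth-muscle genes gave 9 higher and 7 lower of 20, collagens and matrix structure 17 and 17 of 41, and matrix proteases and inhibitors 13 and 8 of 32. Among the proteases, Mmp9 rose by 1.88 ± 0.55 (adjusted p = 0.00873). The ADAM family gave 4 higher and 2 lower of 10, inflammatory cytokines 12 and 8 of 34, Wnt 9 and 6 of 30, and targets of TGF-beta and BMP 7 and 9 of 24. Ccl5, a chemokine, rose by 1.83 ± 0.19 and Ccl2 fell by 0.24. Il6 had a log2 change of -0.19 ± 0.60 (adjusted p = 0.836), Cnn1 of 0.53 ± 0.37 (0.273) and Myh11 of 0.64 ± 0.66 (0.478). NRF2 targets gave 7 higher and 12 lower of 26, Notch targets 5 and 2 of 12, osteochondrogenic markers 5 and 2 of 13, EGFR ligands and receptors 4 and 4 of 13, and integrins 7 and 1 of 17. The integrin Itga10 rose from 2.19 ± 0.44 to 17.5 ± 2.26 CPM. Mitochondrially encoded genes gave 5 higher and 1 lower of 13, with a median of 0.03 and a mean of -0.03, and ribosomal protein genes 4 and 15 of 40. Endothelial markers gave 2 higher and 1 lower of 9, macrophage markers 2 and 0 of 6, and epithelial markers 1 and 0 of 5. Outside the lists, Ptgds, prostaglandin D synthase, rose by 4.49 ± 0.56, Ces1d by 4.34 ± 0.24, a carboxylesterase with close paralogs whose reads it may share, and Angptl4, an inhibitor of lipoprotein lipase, fell by 2.35.

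In WT cells rhCTHRC1 also lowered Acta2 and Tagln. Acta2 fell from 235 ± 32.5 to 48.6 ± 5.02 CPM (log2 change -2.29 ± 0.12, adjusted p = 7.47e-08), and Tagln by 2.17 on the log2 scale. Mmp2 rose from 233 ± 2.63 to 478 ± 19.0 CPM (log2 change 1.02 ± 0.03, adjusted p = 5.95e-16). Against the vehicle libraries of Rosa26-KO or of ADAM9i cells, Acta2 fell by 3.09 or 3.27 on the log2 scale, Tagln by 2.38 or 2.68, and Mmp2 rose by 0.71 or 0.72. In all, 11852 of 18816 tested genes changed against WT vehicle, 6053 higher and 5799 lower, and 4732 at least 2-fold. With the other controls 9964 (4851 higher, 5113 lower) or 10024 genes (4886 higher, 5138 lower) changed, and scaling by library size alone gave 7369 higher and 4637 lower against WT vehicle.

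Of the 35 interferon-response genes, 33 rose and 0 fell in WT cells, and 33 adjusted over the list alone (adjusted p = 2.86e-09 in camera, adjusted p = 0.212 with an estimated correlation). With Rosa26-KO or ADAM9i vehicle as the control, 34 or 32 rose. Irf7, a master regulator of interferon genes, rose from 5.73 ± 0.49 to 42.2 ± 3.69 CPM, and Zbp1 by 2.99 ± 0.25 on the log2 scale, with 3.10 and 2.41 for Irf7 and 3.9 and 1.69 for Zbp1 in the other controls. Of 30 immediate early and ERK feedback genes, 18 rose and 5 fell, and 18 and 5 adjusted over the list alone (adjusted p = 0.042 in camera, adjusted p = 0.522 with an estimated correlation). With either other control 23 rose and 4 fell. Egr2 and Egr3, growth-factor-induced transcription factors, rose by 3.35 ± 0.20 and 3.99 ± 0.25, and with the other controls Egr2 by 3.28 or 3.97 and Egr3 by 2.61 or 2.74. Atf3 fell by 3.42 against WT vehicle, and was higher by 0.45 or 1.01 with the other controls. Of 35 inflammatory cytokines and NF-kB targets 24 rose and 5 fell, and 24 and 5 adjusted over the list alone (adjusted p = 0.000754 in camera, adjusted p = 0.212 with an estimated correlation). The other controls gave 25 and 3, or 16 and 7. The chemokines Cxcl1 and Ccl2 rose by 3.30 ± 0.07 and 1.47 ± 0.09, and Cxcl1 by 2.23 or 1.85 with the other controls. With ADAM9i vehicle as the control, the change of Ccl2 was 0.14 ± 0.08 (adjusted p = 0.142).

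For other gene groups of the WT response, the level in the WT vehicle libraries decided the size or the direction. All 30 genes of the unfolded protein and ATF4 response fell, and 30 adjusted over the list alone (adjusted p = 1.22e-14 in camera, adjusted p = 0.0125 with an estimated correlation). With Rosa26-KO or ADAM9i vehicle as the control 22 or 17 fell, and 6 or 10 rose, and the list passed with the first (adjusted p = 4.62e-05 in camera, adjusted p = 0.196 with an estimated correlation) but not with the second (adjusted p = 0.0716 in camera). Chac1 was higher by 1.76 or 2.44 and Herpud1, of protein degradation at the endoplasmic reticulum, by 0.66 or 1.03 with these controls. Hspa5 fell by 2.70 on the log2 scale (adjusted p = 2.35e-21; chromosome 2, 34771970 to 34777547, ENSMUSG00000026864), and by 1.10 or 1.06 with the other controls. Xbp1, a transcription factor of this response, fell by 2.23, and by 0.83 or 0.86 with the other controls. Slc7a11, the cystine transporter, fell by 2.38, had -0.22 with Rosa26-KO vehicle, and was higher by 0.28 with ADAM9i vehicle. All 25 genes of cholesterol synthesis rose, and 25 adjusted over the list alone (adjusted p = 2.52e-14 in camera, adjusted p = 0.0698 with an estimated correlation). With the other controls 5 or 4 rose, and 15 or 16 fell (adjusted p = 0.0146 and 0.00339 in camera, adjusted p = 0.445 and 0.37 with an estimated correlation). Fdps, which makes farnesyl diphosphate, rose from 46.5 ± 1.57 to 360 ± 5.59 CPM, with log2 changes of 0.00 and -0.06 in the other controls, Nsdhl by 3.19 ± 0.05 (0.20 and 0.07), and Acat2, a thiolase, by 2.74 ± 0.05 (-0.33 and -0.36). Of 40 collagens and matrix genes 28 rose and 6 fell, and 28 and 6 adjusted over the list alone (adjusted p = 1.74e-05 in camera, adjusted p = 0.253 with an estimated correlation). With Rosa26-KO vehicle 11 rose and 19 fell (adjusted p = 0.0491 in camera, adjusted p = 0.405 with an estimated correlation), and with ADAM9i vehicle 14 and 17 (adjusted p = 0.475 in camera). Col3a1 rose from 6.12 to 137 CPM, with a change of 0.12 or -0.10 in the other controls. Of 14 fibroblast markers 10 rose and 1 fell, and 10 and 1 adjusted over the list alone (adjusted p = 0.00259 in camera, adjusted p = 0.212 with an estimated correlation). The other controls gave 10 and 2 (adjusted p = 0.0418 in camera, adjusted p = 0.2 with an estimated correlation), or 6 and 1 (adjusted p = 0.188 in camera). Pdgfra, a receptor of platelet-derived growth factor, rose by 2.58 ± 0.05, and by 0.21 or 0.22 with the other controls.

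Of 40 cytosolic ribosomal protein genes, 4 rose and 32 fell in WT cells, and 4 and 32 adjusted over the list alone (adjusted p = 1.07e-05 in camera, adjusted p = 0.408 with an estimated correlation). With the other controls 39 or 40 fell. Rps2 fell by 0.79 and Rpl7a by 0.97 on the log2 scale, and Rps2 by 1.01 or 0.90 and Rpl7a by 0.88 or 0.80 with the other controls. Of 10 tested ADAM family genes 8 rose and 0 fell, and 8 adjusted over the list alone (adjusted p = 0.0261 in camera, adjusted p = 0.253 with an estimated correlation). The other controls gave 6 and 3, or 5 and 1, and the list missed the threshold (adjusted p = 0.434 and 0.242 in camera). Adam11 rose by 2.50 ± 0.29 (1.38 and 1.54 with the other controls) and Adam12 by 2.22 ± 0.13, but Adam12 was lower, with -2.25 and -2.55, in the other controls. Of 24 contractile genes 14 rose and 6 fell, and 14 and 6 adjusted over the list alone (adjusted p = 0.0616 in camera), and 6 and 11, or 7 and 11, with the other controls. Myl9, a myosin light chain, rose by 2.84 ± 0.19 (-0.25 and -0.43 with the other controls), Des, the intermediate filament desmin, by 2.73 ± 0.19 (1.33 and 1.05), and Cnn1 by 1.52 ± 0.62, with libraries of the 2 groups that overlap. Cnn1 lay at 0.51 CPM and lost its call without any of 4 single libraries: WT vehicle replicate 1 or 2, or rhCTHRC1 replicate 1 or 2 (adjusted p = 0.0645 to 0.165), and it was at -0.29 (adjusted p = 0.67) and -1.61 (0.00701) with the other controls. Mmp9 rose by 1.14 ± 0.42 (adjusted p = 0.0228), and missed the threshold without WT vehicle replicate 2 (0.0942) or rhCTHRC1 replicate 2 (0.0679), and with the other controls, at 0.94 (adjusted p = 0.122) and -0.04 (0.959). Il6 fell by 1.30 (adjusted p = 0.00463), and was at 0.98 with Rosa26-KO vehicle as the control (adjusted p = 0.0898) and at -0.48 with ADAM9i vehicle (0.413). Myh11 had 1.04 ± 1.03 (adjusted p = 0.403). Car6, a secreted carbonic anhydrase, fell from 20.3 ± 2.41 to 0.34 ± 0.18 CPM, with changes of -0.47 and -0.98 in the other controls that missed the threshold (adjusted p = 0.52 and 0.136).

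The remaining lists of the WT response missed the threshold in camera. Modulated smooth-muscle genes gave 12 higher and 8 lower of 20, matrix proteases and inhibitors 18 and 8 of 31, Wnt 15 and 9 of 30, and TGF-beta and BMP targets 13 and 9 of 24. Targets of YAP and SRF gave 9 and 10 of 22, with a median of -0.12 and a mean of 0.04. Cell-cycle genes gave 21 and 15 of 38, hypoxia and glycolysis 6 and 13 of 29, and p53 targets 8 and 12 of 25. The control libraries decided some of these. Cell-cycle genes gave 5 higher and 24 lower with Rosa26-KO vehicle (adjusted p = 4.28e-05 in camera, adjusted p = 0.196 with an estimated correlation) and 1 and 33 with ADAM9i vehicle (adjusted p = 9.9e-11 in camera, adjusted p = 0.078 with an estimated correlation). Hypoxia and glycolysis gave 6 and 11 (adjusted p = 0.154 in camera) and 1 and 23 (adjusted p = 6.51e-07 in camera, adjusted p = 0.353 with an estimated correlation). YAP and SRF targets gave 5 and 13 (adjusted p = 0.0491 in camera, adjusted p = 0.521 with an estimated correlation) and 6 and 14 (adjusted p = 0.0841 in camera). NRF2 targets gave 10 and 11 of 26, with a median of 0.01 and a mean of -0.01. Notch targets gave 5 and 0 of 12, osteochondrogenic markers 4 and 3 of 14, EGFR ligands and receptors 6 and 4 of 13, integrins 9 and 4 of 17, and mitochondrially encoded genes 8 and 0 of 13. Endothelial markers gave 1 and 3 of 8, macrophage markers 3 and 1 of 6, and epithelial markers 3 and 1 of 5. In all, 9 of 27 lists passed with the preset correlation, 7 higher and 2 lower, and 1 with an estimated correlation.

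The responses of WT and Rosa26-KO cells were compared across genes, as a measure of how far the response of unedited cells was shared by edited control cells. Genes that rose in both numbered 3013, against 1346 for independent lists, and genes that fell in both 3246, against 1361. Across 18043 genes Pearson's r of the log2 changes was 0.50 and Spearman's rho 0.59, where genes are not independent replicates. With ADAM9i vehicle as the control of the WT libraries, r was 0.469. With either control the responses compared share no library. The difference of the responses passed the threshold in 8720 of 19891 genes, 4325 higher and 4395 lower in Rosa26-KO than in WT cells, and 2382 at least 2-fold. The genes named next were chosen after their values were seen. Egr1 and Fos, immediate early genes, differed by -5.24 ± 0.09 and -5.12 ± 0.46 on the log2 scale (adjusted p = 2.35e-21 and 4.97e-08). Under rhCTHRC1 Fos was at 567 ± 69.7 CPM in WT and 1.06 ± 0.35 CPM in Rosa26-KO cells. Hspa5 differed by 1.83 ± 0.06, Fdps by -2.55 ± 0.05, Col3a1 by -3.69 ± 0.11, Irf7 by -0.83 ± 0.22 and Acta2 by -1.08 ± 0.14, each past the threshold. For Adam9 the difference was 0.04 ± 0.13 (adjusted p = 0.844). With Rosa26-KO vehicle as the control of both responses, that control cancels. What remains is the direct difference of the 2 treated groups, which tests no difference of responses. In it, a choice made after the data were seen, 6448 genes passed, 3641 higher and 2807 lower in Rosa26-KO cells. Fdps (0.40 ± 0.03), Col3a1 (0.68 ± 0.07) and Hspa5 (0.25 ± 0.04) were higher. The negative differences of responses of Fdps and Col3a1 therefore came from the vehicle libraries. Egr1 (-5.44 ± 0.07), Fos (-9.06 ± 0.34) and Irf7 (-1.06 ± 0.15) were lower, and Acta2 missed the threshold (-0.26 ± 0.10, adjusted p = 0.0625). Adam9 was at -0.04 ± 0.09 (adjusted p = 0.837).

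**Figure D3:**
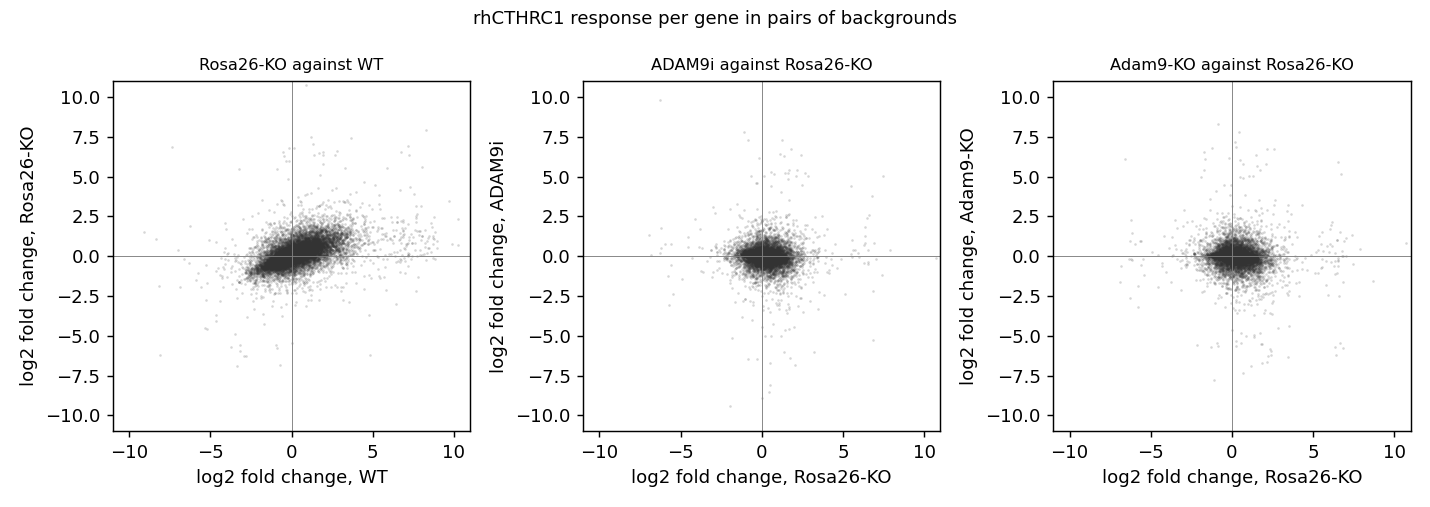
Log2 changes with rhCTHRC1 of each gene in one background against another, each point a gene. Across genes r is 0.50 for WT and Rosa26-KO cells and -0.10 for Rosa26-KO and Adam9-KO cells.

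Under vehicle the Rosa26-KO and WT libraries differed in 10677 of 19891 genes, 5554 higher and 5123 lower in Rosa26-KO cells, and 3161 at least 2-fold. The largest rises among named genes were Cdh26, a cadherin, with 5.08 ± 0.19, Npy4r, a neuropeptide receptor, with 5.04 ± 0.14 and Igfbp5, which binds insulin-like growth factors, with 5.0 ± 0.12. The AP-1 component Fosb was lower by -7.06 ± 0.39 (adjusted p = 3.06e-11), at 1.07 ± 0.16 CPM against 144 ± 30.6 CPM. Of genes chosen after their values were seen, Hspa5 differed by -1.59 ± 0.04, Chac1 by -3.09 ± 0.07, Col3a1 by 4.38 ± 0.09, Nsdhl by 3.01 ± 0.05 and Acta2 by 0.82 ± 0.10, each past the threshold. Adam9 differed by -0.08 ± 0.09 (adjusted p = 0.514).

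In ADAM9i cells rhCTHRC1 changed far fewer genes, and with small folds. Of the targets of YAP and SRF 9 of 22 rose, of immediate early genes 6 of 30, and of interferon-response genes 7 of 35 fell, and no list held with an estimated correlation. Acta2 had a log2 change of -0.29 ± 0.11 (adjusted p = 0.237), from 469 ± 20.3 to 384 ± 25.3 CPM, and Tagln of 0.33 ± 0.13 (adjusted p = 0.2). Spp1, osteopontin, rose from 248 ± 3.0 to 379 ± 11.4 CPM (log2 change 0.61 ± 0.05, adjusted p = 1.73e-05; chromosome 5, 104435118 to 104441050, ENSMUSG00000029304). In all, 749 of 18816 genes changed, 500 higher and 249 lower, and 34 at least 2-fold. DESeq2 called 1210, and leaving out 1 library gave 397 (without the treated replicate 3) to 638, with 423 without treated replicate 1, 423 without vehicle replicate 3 and 453 without vehicle replicate 2.

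Of 22 targets of YAP and SRF, 9 rose and 0 fell in ADAM9i cells, and 14 and 2 adjusted over the list alone (adjusted p = 1.79e-07 in camera, adjusted p = 0.114 with an estimated correlation). Ankrd1 rose by 0.59 ± 0.06 and Tpm1, a tropomyosin, by 0.23 ± 0.03. Ccn2 rose by 0.66 ± 0.14 (adjusted p = 0.0334), and missed the threshold without vehicle replicate 1 or without treated replicate 1, 2 or 3 (0.0617 to 0.119). Of 30 immediate early and ERK feedback genes 6 rose and 0 fell, and 12 and 1 adjusted over the list alone (adjusted p = 1.92e-08 in camera, adjusted p = 0.114 with an estimated correlation). Etv4, a transcription factor downstream of ERK, rose by 0.87 ± 0.08 and Dusp4, a phosphatase of ERK, by 0.55 ± 0.07. Dusp5 rose by 0.52 ± 0.12 (adjusted p = 0.0211), and missed the threshold without vehicle replicate 1 or 3 or treated replicate 1 or 3 (0.066 to 0.105). Of 35 interferon-response genes 0 rose and 7 fell, and 17 fell adjusted over the list alone (adjusted p = 3.38e-10 in camera, adjusted p = 0.114 with an estimated correlation). Irf7 fell by 0.61 (adjusted p = 0.00273) and Ifi27 by 0.35 on the log2 scale. Oasl2 fell by 0.47 (adjusted p = 0.0163), and missed the threshold without vehicle replicate 3 or treated replicate 1 or 2 (0.0678 to 0.0888). Of 30 unfolded protein and ATF4 genes 8 rose and 1 fell, and 15 and 3 adjusted over the list alone (adjusted p = 0.00138 in camera, adjusted p = 0.114 with an estimated correlation). Hspa5 rose by 0.33 ± 0.03 (adjusted p = 3.83e-06). Chac1 rose by 0.27 ± 0.06 (adjusted p = 0.0224), and missed the threshold without vehicle replicate 2 or any 1 treated replicate (0.0507 to 0.119).

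Of 35 inflammatory genes, 9 rose and 4 fell in ADAM9i cells, and 14 and 5 adjusted over the list alone (adjusted p = 0.00275 in camera, adjusted p = 0.183 with an estimated correlation). Traf1, an adaptor of TNF receptors, rose by 1.66 ± 0.21, Ccl5 fell by 1.0 on the log2 scale, and Ccl2 rose by 0.51 ± 0.09 (adjusted p = 0.0092, and 0.0501 without vehicle replicate 2). Cholesterol synthesis gave 4 higher and 0 lower of 25, and 6 and 0 adjusted over the list alone (adjusted p = 0.000199 in camera, adjusted p = 0.198 with an estimated correlation). The p53 targets gave 4 and 0 of 25, and 7 and 1 adjusted over the list alone (adjusted p = 0.00225 in camera, adjusted p = 0.114 with an estimated correlation). Cdkn1a, which encodes p21, rose by 0.65 ± 0.13 (adjusted p = 0.0109, and 0.0555 without treated replicate 1). EGFR ligands and receptors gave 4 and 0 of 13, and 4 and 0 adjusted over the list alone (adjusted p = 0.00557 in camera, adjusted p = 0.114 with an estimated correlation). Hbegf, an EGFR ligand, rose by 0.45 ± 0.10 (adjusted p = 0.0163), and missed the threshold without vehicle replicate 2 or 3 or treated replicate 1 or 3 (0.0589 to 0.0966). A shift in the same test was found for contractile genes (3 rose and 0 fell of 24), TGF-beta and BMP targets (1 and 0 of 24), integrins (2 and 0 of 17), and hypoxia and glycolysis (0 and 1 of 29, with a median of 0.08), all toward higher values with adjusted p of 0.0177 to 0.0315 in camera. Cell-cycle genes (4 and 2 of 38), ribosomal protein genes (0 and 1 of 40) and fibroblast markers (0 and 3 of 14) shifted toward lower values, with adjusted p of 0.0129 to 0.0376. With an estimated correlation 0 of the 15 lists past the threshold held, with adjusted p of 0.114 to 0.639. Ccnd1, cyclin D1, rose by 0.47 ± 0.04.

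The other lists missed the threshold in ADAM9i cells: modulated smooth-muscle genes gave 2 higher and 2 lower of 20, collagens 5 and 4 of 40, and the ADAM family 0 and 0 of 10. Matrix proteases gave 5 and 1 of 31, with a median of -0.01 and a mean of 0.04, and Mmp10 rose by 0.87 ± 0.15. Mmp2 fell by 0.13 (adjusted p = 0.0219), and missed the threshold without vehicle replicate 2 or 3 or treated replicate 2 or 3 (0.0643 to 0.0944). Mmp9 had -0.14 ± 0.40 (adjusted p = 0.93), Il6 -0.25 ± 0.37 (0.842), Cnn1 0.20 ± 0.52 (0.925) and Myh11 -0.95 ± 1.07 (0.778). Wnt gave 1 and 1 of 30, NRF2 targets 5 and 2 of 26, Notch targets 0 and 0 of 12 (median -0.02, mean 0.07), osteochondrogenic markers 1 and 0 of 14, and mitochondrially encoded genes 0 and 0 of 13. Endothelial markers gave 1 and 0 of 8 (median -0.15, direction of the test higher), macrophage markers 0 and 1 of 6, and epithelial markers 0 and 0 of 5. Of single genes outside the lists, Angptl4 rose by 0.95 ± 0.16, Avil, advillin, fell by 1.51 and Akr1b7, an aldo-keto reductase, by 1.40. Padi2 rose by 1.72 ± 0.46 (adjusted p = 0.0414), which DESeq2 did not call and which missed the threshold without vehicle replicate 1, 2 or 3 or treated replicate 1 or 3 (0.058 to 0.153). Between the WT and ADAM9i responses r across 18816 genes was -0.05 and Spearman's rho -0.18, with r of -0.258 for genes of at least 10 CPM. Leaving out 1 library gave r of -0.074 (without ADAM9i treated replicate 1) to -0.012 (without ADAM9i vehicle replicate 2). Genes that fell in WT and rose in ADAM9i cells numbered 338, against 154 for independent lists (Fisher's exact test, one-sided, p = 7.36e-66, where genes are not independent), and those that rose in WT and fell in ADAM9i cells 168, against 80 (p = 1.74e-30). With Rosa26-KO vehicle as the control of the WT libraries, chosen after the result was seen, r was -0.041 and rho -0.14, and these numbers were 330 against 135 (p = 6.54e-76) and 172 against 64 (p = 2.14e-47).

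The difference of the responses of ADAM9i and WT cells passed the threshold in 10540 of 18816 genes, 5222 higher and 5318 lower in ADAM9i cells, and 4623 at least 2-fold. Hspa5 differed by 3.04 ± 0.04 on the log2 scale (adjusted p = 9.17e-20), Xbp1 by 2.46 ± 0.06 and Acta2 by 2.0 ± 0.16. Irf7 differed by -3.47 ± 0.15, Col3a1 by -4.80 ± 0.12, Nsdhl by -3.11 ± 0.07, Fdps by -2.89 ± 0.05, Pdgfra by -2.79 ± 0.07 and the chemokine Cxcl1 by -3.35 ± 0.09. With the Rosa26-KO response in place of the WT response 7049 genes passed, 3792 higher and 3257 lower. The differences were then 1.19 ± 0.06 for Hspa5, 0.86 ± 0.07 for Xbp1, 3.06 ± 0.14 for Acta2, -2.65 ± 0.22 for Irf7, -1.13 ± 0.10 for Col3a1, -0.41 ± 0.06 for Nsdhl, -0.35 ± 0.05 for Fdps and -0.87 ± 0.06 for Pdgfra, and 0.22 ± 0.10 for Cxcl1 (adjusted p = 0.0891). Of the gene lists, 7 passed, 2 higher and 5 lower. The unfolded protein and ATF4 list had 29 higher and 0 lower of 30, and 29 adjusted over the list alone (adjusted p = 1.13e-15 in camera, adjusted p = 0.00994 with an estimated correlation). Cholesterol synthesis had 0 higher and 25 lower of 25, and 25 adjusted over the list alone (adjusted p = 7.9e-15 in camera, adjusted p = 0.0633 with an estimated correlation), and the interferon response 0 and 31 of 35, and 32 adjusted over the list alone (adjusted p = 1.28e-10 in camera, adjusted p = 0.157 with an estimated correlation). Ribosomal proteins were higher in 28 and lower in 3 of 40, and collagens (8 and 25 of 40), fibroblast markers (1 and 10 of 14) and inflammatory genes (5 and 19 of 35) mostly lower, with adjusted p of 0.000171 to 0.0211 in camera and adjusted p of 0.157 to 0.552 with an estimated correlation. With the Rosa26-KO response in place of the WT response, collagens (17 higher and 15 lower), inflammatory genes (8 and 11) and ribosomal proteins (7 and 4) missed the threshold (adjusted p = 0.84, 0.643 and 0.643 in camera). The unfolded protein list then had 29 and 0 (adjusted p = 8.53e-28 in camera, adjusted p = 0.00111 with an estimated correlation), the interferon response 0 and 34 (adjusted p = 9.19e-21 in camera, adjusted p = 0.0302 with an estimated correlation), cholesterol synthesis 0 and 15 (adjusted p = 7.55e-05 in camera, adjusted p = 0.306 with an estimated correlation), and fibroblast markers 1 and 9 (adjusted p = 0.00173 in camera, adjusted p = 0.068 with an estimated correlation). Another 5 lists passed only in that form, all higher. Of these, p53 targets had 15 and 2 (adjusted p = 0.000496 in camera, adjusted p = 0.00864 with an estimated correlation), immediate early genes 18 and 2 (3.71e-07 in camera, against 6 and 13 with WT), cell-cycle genes 26 and 2 (2.34e-07, against 14 and 21), YAP and SRF targets 13 and 2 (9.69e-05), and hypoxia and glycolysis 15 and 1 (0.000184). For the last 4, adjusted p was 0.068 to 0.573 with an estimated correlation. Scaling by library size alone gave 4113 higher and 6558 lower.

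In Adam9-KO cells no gene passed the threshold for a response to rhCTHRC1. Acta2 was at 425 ± 12.8 CPM under vehicle and 380.2 ± 45.8 CPM with rhCTHRC1 (log2 change -0.15 ± 0.07, adjusted p = 0.659), Mmp2 at 302 ± 8.70 and 289 ± 19.1 CPM (-0.06 ± 0.04, adjusted p = 0.773), and Tagln had -0.12 ± 0.17 (adjusted p = 0.935). edgeR called 0 of 18594 genes at an adjusted p of 0.05, with 1387 at an unadjusted p under 0.05. DESeq2 called 37 (13 higher, 24 lower), limma on FPKM 0, and edgeR fitted to the 6 libraries alone 1. Leaving out 1 library gave 0 to 3 calls, the 3 without treated replicate 1. Treated replicate 3 lay apart from replicates 1 and 2 on the second principal component, at 32.4 against 14.6 and 12.3. It had Irf7 at 3.37 CPM, against 6.53 and 6.04 CPM, and the means and list shifts given here include it. The genes with the smallest p were Ndnf (-0.30 ± 0.06), Nek6 (0.21 ± 0.04), Pdap1 (0.19 ± 0.04) and Rapgef3 (-0.36 ± 0.07), each with an adjusted p of 0.243 in edgeR and of 0.00435 in DESeq2. Cnn1 had 0.33 ± 0.36, Myh11 0.10 ± 0.66, Ccl2 0.00 ± 0.06, Il6 -0.21 ± 0.59 and Mmp9 -0.53 ± 0.54, with adjusted p of 0.89 to 0.995. Of the 27 lists, 6 passed in camera, each with 0 members called over all genes. Cell-cycle genes (median 0.04, adjusted p = 0.000158), cholesterol synthesis (0.06, 0.000277) and ribosomal proteins (0.02, 0.012) shifted higher. Interferon-response genes (-0.10, 0.00234), collagens (-0.04, 0.00368) and matrix proteases (-0.08, 0.01) shifted lower. With an estimated correlation 0 of these 6 held (adjusted p = 0.382 to 0.48). Adjusted over the list alone, 5 collagen and matrix genes and 1 protease gene were called lower, and 0 genes of the other 4 lists. Of the lists that missed the threshold in camera, hypoxia and glycolysis had 7 higher and 1 lower genes in that narrower adjustment. In data simulated with the spread of these libraries, edgeR found 38 of 50 changed 1.5-fold and 45 of 50 changed 2-fold. The changed genes were drawn only from those with a mean of at least 50 counts, so these shares do not cover genes with fewer counts. Each gene was drawn independently, with no library set to deviate. Across 18594 genes r between the Rosa26-KO and Adam9-KO responses was -0.10, with -0.339 for genes of at least 10 CPM and, leaving out 1 library, -0.139 (without Adam9-KO treated replicate 1) to -0.032 (without Adam9-KO vehicle replicate 2). Between the ADAM9i and Adam9-KO responses it was -0.05 across 18043 genes, but 0.165 for genes of at least 10 CPM, so its sign depends on the genes used.

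The response to rhCTHRC1 differed between Adam9-KO and Rosa26-KO cells in 7050 of 18594 genes, 3743 higher and 3307 lower in Adam9-KO cells, and 1249 at least 2-fold. Acta2 differed by 3.20 ± 0.10 on the log2 scale (adjusted p = 3.82e-10), Myocd by 2.22 ± 0.46 and Tagln by 1.32 ± 0.24. The unfolded protein and ATF4 list had 29 higher and 0 lower of 30, and 29 adjusted over the list alone (adjusted p = 6.98e-20 in camera, adjusted p = 0.0732 with an estimated correlation), with Chac1 at 2.19 ± 0.10 and Trib3 at 2.05 ± 0.15. The interferon response had 0 higher and 33 lower of 35, and 33 adjusted over the list alone (adjusted p = 3.76e-16 in camera, adjusted p = 0.11 with an estimated correlation), with Zbp1 at -3.21 ± 0.57 and Ifi44 at -3.11 ± 0.54. Cell-cycle genes were higher in 31 and lower in 1 of 38, with 32 and 2 adjusted over the list alone (adjusted p = 2.44e-10 in camera, adjusted p = 0.131 with an estimated correlation), Rrm2 by 0.79 ± 0.08. Cholesterol synthesis had 0 higher and 17 lower of 25, and 17 adjusted over the list alone (adjusted p = 2.09e-05 in camera, adjusted p = 0.436 with an estimated correlation), with Insig1 at -1.17 ± 0.04. Hypoxia and glycolysis gave 16 higher and 2 lower of 28, with Ldha at 1.45 ± 0.07, immediate early genes 17 and 4 of 29, with Fosl1 at 2.54 ± 0.21, p53 targets 14 and 2 of 25, YAP and SRF targets 11 and 4 of 22, ribosomal proteins 15 and 2 of 40, and fibroblast markers 1 and 9 of 14. Their adjusted p in camera were 0.000218 to 0.0217, and adjusted p of 0.11 to 0.524 with an estimated correlation. Of the other genes, Ces1d differed by -4.70 ± 0.32, Ptgds by -4.62 ± 0.77, and Mmp9 by -2.41 ± 0.77 (adjusted p = 0.0187), which missed the threshold without Rosa26-KO vehicle replicate 2, Rosa26-KO treated replicate 2 or Adam9-KO vehicle replicate 2 (0.0508 to 0.0548). Scaling by library size alone gave 2916 higher and 4153 lower.

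**Figure D4:**
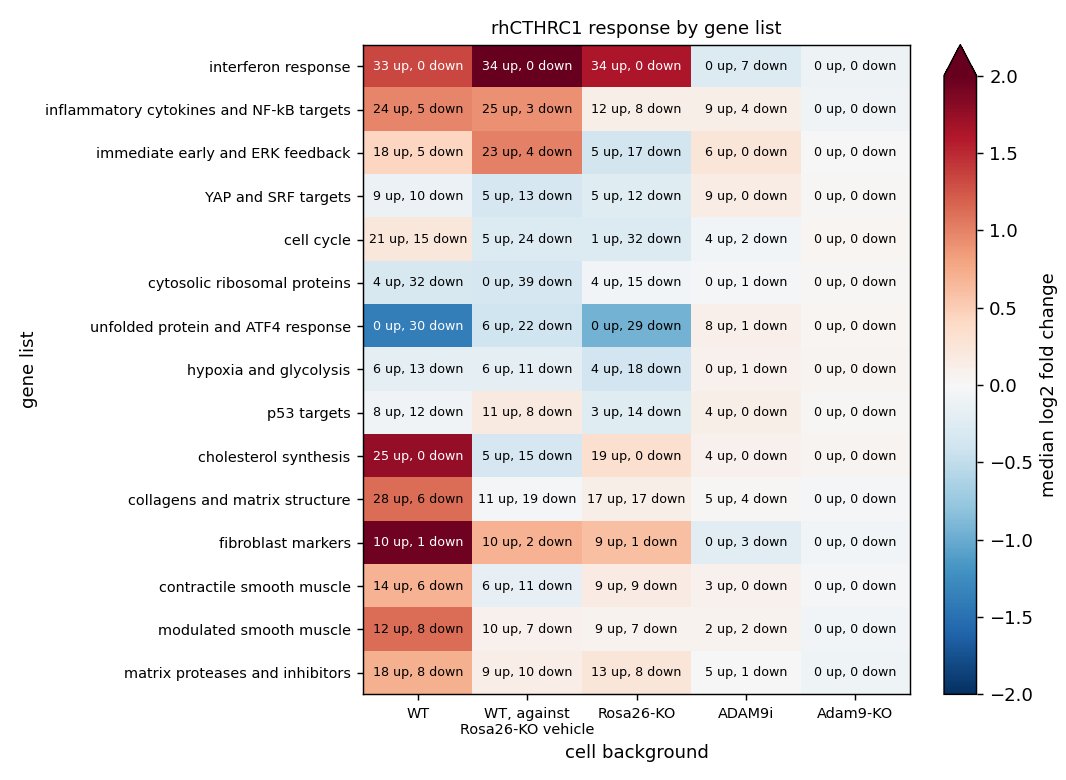
Median log2 change with rhCTHRC1 (colour) and number of genes called higher and lower (text) for 15 gene lists, in WT cells against WT vehicle and against Rosa26-KO vehicle, and in Rosa26-KO, ADAM9i and Adam9-KO cells. The Adam9-KO column holds 0 called genes.

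Under vehicle, ADAM9i cells differed from WT cells in 10804 of 18816 genes, 5634 higher and 5170 lower, and 3283 at least 2-fold. Against the Rosa26-KO vehicle libraries in place of WT vehicle the count was 3031, 1455 higher and 1576 lower. Chac1 was lower by -3.78 ± 0.06 on the log2 scale against WT and by -0.69 ± 0.07 against Rosa26-KO vehicle, and Herpud1 by -2.57 ± 0.04 and -0.37 ± 0.05. Fgf21, a hormone induced through ATF4, was at 0.38 ± 0.22 CPM against 48.8 ± 2.92 CPM in WT (-7.01 ± 0.31) and differed by -1.27 ± 0.35 against Rosa26-KO vehicle. Of 30 unfolded protein and ATF4 genes 1 was higher and 24 lower, and 1 and 24 adjusted over the list alone (adjusted p = 4.02e-12 in camera, adjusted p = 0.025 with an estimated correlation), and 0 and 21 against Rosa26-KO vehicle. All 25 genes of cholesterol synthesis were higher, and 25 adjusted over the list alone (adjusted p = 5.06e-17 in camera, adjusted p = 0.0269 with an estimated correlation), but 4 higher and 3 lower against Rosa26-KO vehicle. Nsdhl and Acat2 differed by 3.13 ± 0.05 and 3.11 ± 0.05 against WT, and by 0.13 ± 0.04 and 0.03 ± 0.04 against Rosa26-KO vehicle. Of 24 contractile genes 19 were higher and 2 lower, and 19 and 2 adjusted over the list alone (adjusted p = 8.32e-05 in camera, adjusted p = 0.0269 with an estimated correlation), with 2 and 2 against Rosa26-KO vehicle. Myl9 differed by 3.28 ± 0.19, and by 0.18 ± 0.13 against Rosa26-KO vehicle.

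Further lists that separated ADAM9i from WT vehicle were cell-cycle genes (31 higher and 6 lower of 38, and 19 and 1 against Rosa26-KO vehicle), collagens (34 and 4 of 40, and 4 and 23), and hypoxia and glycolysis (22 and 5 of 29, and 25 and 1). Modulated smooth-muscle genes (15 and 3 of 20), matrix proteases (18 and 8 of 31), inflammatory genes (21 and 9 of 35), mitochondrially encoded genes (11 and 0 of 13) and fibroblast markers (9 and 2 of 14) were also mostly higher than in WT, and immediate early genes mostly lower (5 and 19 of 30). These 9 lists had adjusted p of 1.15e-08 to 0.0383 in camera and adjusted p of 0.115 to 0.712 with an estimated correlation. Against Rosa26-KO vehicle, the collagens were lower (adjusted p = 5.72e-10 in camera), the inflammatory genes stayed higher, with 17 and 2 (adjusted p = 4.7e-10 in camera, adjusted p = 0.0118 with an estimated correlation), and 5 of the lists missed the threshold. These were modulated smooth-muscle genes (6 and 5, adjusted p = 0.432 in camera), matrix proteases (8 and 8, 0.549), mitochondrially encoded genes (0 and 1, 0.144), fibroblast markers (3 and 2, 0.432) and immediate early genes (7 and 5, 0.432). Hypoxia and glycolysis passed in camera (adjusted p = 1.03e-20) but not with an estimated correlation (adjusted p = 0.0563). Cell-cycle genes passed in both (adjusted p = 3.23e-09 in camera, adjusted p = 0.0376 with an estimated correlation). Of lists that did not pass against WT vehicle, the interferon response had 21 and 1 (adjusted p = 4.15e-13 in camera, adjusted p = 0.0588 with an estimated correlation), against 10 and 16 with WT, TGF-beta and BMP targets 2 and 10 (adjusted p = 0.000761 in camera, adjusted p = 0.0233 with an estimated correlation), and ribosomal proteins 16 and 1 (adjusted p = 1.62e-05 in camera, adjusted p = 0.321 with an estimated correlation). Mki67 and Aurkb, a mitotic kinase, differed by 1.83 ± 0.03 and 1.84 ± 0.05, and by 0.11 ± 0.03 and 0.24 ± 0.04 against Rosa26-KO vehicle. Col3a1 differed by 4.58 ± 0.10, and by 0.21 ± 0.07 against Rosa26-KO vehicle. Pdgfra differed by 2.37 ± 0.05 and -0.01 ± 0.04. Fos was lower by -2.30 ± 0.32 against WT and higher by 1.64 ± 0.29 against Rosa26-KO vehicle, and Atf3 lower by -4.42 ± 0.16 and -0.56 ± 0.13.

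Under vehicle, most immediate early genes were lower in Adam9-KO than in Rosa26-KO cells. Of 29 immediate early and ERK feedback genes 0 were higher and 19 lower in Adam9-KO than in Rosa26-KO cells, and 0 and 22 adjusted over the list alone (adjusted p = 8.11e-12 in camera, adjusted p = 0.0155 with an estimated correlation). Fosl1 was at 9.38 ± 1.28 CPM against 21.2 ± 1.80 CPM (log2 difference -1.19 ± 0.15, adjusted p = 5.33e-05; chromosome 19, 5447547 to 5455946, ENSMUSG00000024912), Fos differed by -1.12 ± 0.23 and Dusp6, a phosphatase of ERK, by -0.95 ± 0.12. Of 22 YAP and SRF targets 1 was higher and 11 lower, and 1 and 14 adjusted over the list alone (adjusted p = 9.4e-06 in camera, adjusted p = 0.452 with an estimated correlation). Ankrd1 differed by -0.54 ± 0.09 and Ccn1 by -0.63 ± 0.12. Ccn2 differed by -0.82 ± 0.17 (adjusted p = 0.0131), and missed the threshold without Adam9-KO vehicle replicate 1 or 2 (0.0506 and 0.0539). In all, 2825 of 18594 genes differed, 1184 higher and 1641 lower, and 119 at least 2-fold. Scaling by library size alone gave 1764 higher and 1011 lower, so the balance of higher and lower calls depends on the scaling. Leaving out Adam9-KO vehicle replicate 1 or 2 gave 1760 or 1788 calls.

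Of 34 inflammatory genes, 1 was higher and 12 lower in Adam9-KO than in Rosa26-KO cells under vehicle, and 1 and 12 adjusted over the list alone (adjusted p = 0.00252 in camera, adjusted p = 0.262 with an estimated correlation). Saa3 and Lcn2, acute-phase proteins, differed by -1.01 ± 0.12 and -1.0 ± 0.12, and Cxcl1 by -0.93 ± 0.08. Hp, haptoglobin, differed by -1.50 ± 0.11. Of 35 interferon-response genes 8 were higher and 0 lower, and 12 adjusted over the list alone (adjusted p = 0.000511 in camera, adjusted p = 0.495 with an estimated correlation). These calls were close to the threshold. Ifi44 (1.17 ± 0.38, adjusted p = 0.0478) missed it without any 1 of the 6 libraries (0.0666 to 0.15), Mx2 (0.95 ± 0.30, adjusted p = 0.0392) without Rosa26-KO or Adam9-KO vehicle replicate 1 or 2 (0.102 to 0.137), and Dhx58 (0.60 ± 0.17, adjusted p = 0.0258), whose libraries overlap between the groups, without Rosa26-KO replicate 1 or 3 or Adam9-KO replicate 1 or 2 (0.0805 to 0.12). Cell-cycle genes gave 0 higher and 8 lower of 38, with Ccne2 at -0.53 ± 0.11, hypoxia and glycolysis 1 and 11 of 28, with Ldha at -0.46 ± 0.05, mitochondrially encoded genes 0 and 7 of 13, and ribosomal proteins 0 and 12 of 40. Their adjusted p were 5.91e-05 to 0.00492 in camera, and adjusted p of 0.262 to 0.452 with an estimated correlation. Endothelial markers gave 1 and 0 of 9 (adjusted p = 0.0205 in camera, adjusted p = 0.262 with an estimated correlation), the called one being Flt1, with 0.22 ± 0.05. Has2, a hyaluronan synthase, differed by -1.68 ± 0.31, Sprr2b, of a family of near-identical paralogs, by -2.82 ± 0.29, and Dusp15 by 1.60 ± 0.28. Sox8 differed by 1.74 ± 0.43 (adjusted p = 0.0109), which DESeq2 did not call, and which was at 0.0502 without Rosa26-KO vehicle replicate 2. Hbegf differed by -0.51 ± 0.13 (adjusted p = 0.00978, and 0.0723 without Rosa26-KO vehicle replicate 2).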

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

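The differences of responses, their gene lists, the DESeq2, limma and leave-one-out fits and the thinning to the smallest total count were planned, and all other tests in this part were chosen after the result was seen. The differences of responses were tested in edgeR as interactions, and 10540 genes passed for ADAM9i minus WT, 7050 for Adam9-KO minus Rosa26-KO and 8720 for Rosa26-KO minus WT. Of the gene lists, 7 passed for ADAM9i minus WT and 10 for Adam9-KO minus Rosa26-KO. Between ADAM9i and WT cells the response differed on the log2 scale by 3.04 for Hspa5, 2.46 for Xbp1, 2.0 for Acta2, -3.11 for Nsdhl, -2.89 for Fdps, -3.47 for Irf7, -4.80 for Col3a1, -3.35 for Cxcl1 and -2.79 for Pdgfra. With the Rosa26-KO response in place of the WT response these were 1.19, 0.86, 3.06, -0.41, -0.35, -2.65, -1.13, 0.22 and -0.87 in the same order, and Cxcl1 missed the threshold (adjusted p = 0.0891). Between Adam9-KO and Rosa26-KO cells it differed by 3.20 for Acta2, 2.22 for Myocd, 1.32 for Tagln, 2.19 for Chac1, 2.05 for Trib3, 1.45 for Ldha, 2.54 for Fosl1 and 0.79 for Rrm2. It differed by -3.21 for Zbp1, -3.11 for Ifi44, -4.70 for Ces1d, -4.62 for Ptgds, -2.41 for Mmp9, -1.17 for Insig1 and -0.24 for Adam9. The call of Mmp9 was lost without Rosa26-KO vehicle replicate 2 (adjusted p = 0.0508), Rosa26-KO treated replicate 2 (0.052) or Adam9-KO vehicle replicate 2 (0.0548). Between Rosa26-KO and WT cells it differed by 1.83 for Hspa5, -2.55 for Fdps, -3.69 for Col3a1, -0.83 for Irf7, -1.08 for Acta2, -5.24 for Egr1 and -5.12 for Fos. The treated groups compared directly, which tests no difference of responses, differed in 6448 genes. Fdps (0.40), Col3a1 (0.68) and Hspa5 (0.25) were higher in treated Rosa26-KO than in treated WT cells, and Acta2 missed the threshold (-0.26, adjusted p = 0.0625). The negative differences of responses of Fdps and Col3a1 therefore came from the vehicle libraries.

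Splits of the same libraries were counted for each comparison, with the real split among them. For ADAM9i minus WT, 1 of 100 splits gave as many genes (10540, highest other 10295), and for Adam9-KO minus Rosa26-KO 2 of 100 did (7050, highest other 7140). For Rosa26-KO minus WT, 8 of 100 did (8720, highest other 12165). Those splits exchange treated and vehicle libraries within a background, so a split that leaves 1 background whole carries its full response, a structure of the samples. Whether chance can be excluded for these differences is therefore not decided by the splits. The 75 splits of each comparison that leave no background whole gave at most 1 (ADAM9i minus WT), 2 (Adam9-KO minus Rosa26-KO) and 1 (Rosa26-KO minus WT) genes. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split and the highest other gave 11852 and 1 genes for the WT response, 749 and 25 for ADAM9i, 8413 and 0 for Rosa26-KO, and 0 and 1 for Adam9-KO, where all 10 splits gave as many. They gave 10804 and 1 for ADAM9i against WT vehicle, 2825 and 1 for Adam9-KO against Rosa26-KO vehicle, and 10677 and 1 for Rosa26-KO against WT vehicle.

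The WT vehicle libraries stood apart, with high unfolded protein and ATF4 genes and low cholesterol-synthesis genes and collagens. Depth is argued against, because thinning every library to the smallest total, 53135752 counts, gave 10753 called genes between ADAM9i and WT vehicle, against 10804 before. A lasting difference between the WT and Rosa26-KO cells is argued against as the whole cause, because across 10181 genes the Rosa26-KO minus WT difference under rhCTHRC1 followed that under vehicle with a slope of only 0.19. A swap of labels stays open: 1 of 24 libraries correlated best with a library of another group, an Adam9-KO library, and an exchange of whole groups would leave no such trace. A difference in culture or handling of the WT vehicle wells may have raised the unfolded protein and ATF4 list. The median of that list was 1.09 higher than in Rosa26-KO vehicle. Such a difference cannot be told apart from the group. The C and T in the WT titles may mark one, but their meaning is not known and they change with the treatment.

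No gene passed the threshold for the response of Adam9-KO cells in edgeR, against 37 in DESeq2 and 0 in limma. Too little power to see a response of the size in Rosa26-KO cells is argued against, because the difference of responses passed for 55.8% of 2115 genes chosen in libraries outside the knockout experiment (at least 2-fold between rhCTHRC1-treated WT and ADAM9i vehicle), while a smaller response stays possible. Treated replicate 3 deviated from its group. That it hid a response of that size is argued against, because 0 genes were called without it. Leaving out 1 library in the Rosa26-KO response still gave 7555 or more. With fewer libraries, a smaller hidden response stays possible. A need for ADAM9 in the response is a candidate explanation these values do not decide. Of the 1205 genes changed at least 2-fold in Rosa26-KO cells, 91.8% had under 0.5 of that log2 change with the inhibitor. In WT cells 19.5% did, or 28% against ADAM9i vehicle. Choosing genes by that change favours smaller values elsewhere. Larger changes in WT cells over all genes (median size 0.635, against 0.327 in Rosa26-KO) lower the 19.5%. Sign was ignored, so opposite changes, such as Egr1 in WT cells, count as kept. Other targets of the inhibitor were not tested. Wells that received no active protein cannot be told apart from a lost response, with 1387 genes at an unadjusted p under 0.05 where chance gives 930. No separate measure of the protein's activity is in the data.

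Under vehicle the Adam9-KO libraries were shifted from Rosa26-KO, across genes and in part, in the direction of the rhCTHRC1 response. Shared control libraries are argued against, because r across genes was 0.54 with a response that shares no library, rhCTHRC1-treated WT against ADAM9i vehicle. The slope was only 0.18, and not all lists followed that response. Called immediate early and inflammatory genes were nearly all lower in Adam9-KO vehicle. In treated WT against ADAM9i vehicle, 23 immediate early genes rose and 4 fell, and 16 inflammatory genes rose and 7 fell. Called interferon-response genes were higher in both comparisons. Set against the Rosa26-KO response the reading differs. Most called immediate early genes fell there too, while inflammatory genes moved in both directions. That response shares the Rosa26-KO vehicle libraries with the shift, so it is not an independent reference. Mixing of RNA from treated cells into the Adam9-KO vehicle libraries is argued against. Rising genes implied a share of 13.8% to 23.0% over the 3 libraries and falling genes 35.7% to 39.6%, a difference of -19.2 percentage points, and Acta2 implied -6.5% to 0.264%. An effect of the Adam9 edit stays open and was not tested.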

How the results depend on the processing

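The other controls and the scaling by library size alone were chosen after seeing the data, and the other alternatives before. RLE size factors, no filter on low counts, limma on FPKM and the replicate block kept each count of called genes within 1.5 times its main value. With the replicate block the responses gave 11826 (WT), 728 (ADAM9i), 8446 (Rosa26-KO) and 0 (Adam9-KO) genes. In no comparison did all libraries of the same replicate number correlate over 0.1 in their deviations from the group mean. Rosa26-KO against WT vehicle came closest, with r of 0.1 to 0.32, against -0.22 to 0.12 for other numbers. A pairing by number is not excluded there. The pseudocount alternative did not apply, because the table has counts.

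A fold of at least 2 left 4732 genes in the WT response, 34 in ADAM9i, 1205 in Rosa26-KO, 4623 for ADAM9i minus WT, 1249 for Adam9-KO minus Rosa26-KO, 3283 for ADAM9i against WT vehicle, 119 for Adam9-KO against Rosa26-KO vehicle, 3161 for Rosa26-KO against WT vehicle and 2382 for Rosa26-KO minus WT, since it adds a criterion. DESeq2 called 1210 genes in ADAM9i and 37 in Adam9-KO, and a fit to the groups compared alone called 1 in Adam9-KO. The cause was not tested. With Rosa26-KO vehicle as the control, ADAM9i against WT vehicle gave 3031 genes. With an estimated correlation the gene lists past the threshold numbered 1 (WT), 0 (ADAM9i), 0 (Rosa26-KO), 0 (Adam9-KO), 1 (ADAM9i minus WT), 0 (Adam9-KO minus Rosa26-KO), 3 (ADAM9i against WT vehicle) and 1 (Adam9-KO against Rosa26-KO vehicle). With genes of at least 10 CPM, r was 0.687 for WT and Rosa26-KO, -0.258 for WT and ADAM9i, -0.339 for Rosa26-KO and Adam9-KO, and 0.165 for ADAM9i and Adam9-KO, a reversed sign. With ADAM9i vehicle as the control of WT, r with Rosa26-KO was 0.469.

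Adam9 in WT cells passed at 0.39 with library size alone. Treated WT cells were higher by 0.30 than Rosa26-KO vehicle and by 0.82 than ADAM9i vehicle, where Adam9 was itself lower than in WT vehicle. With library size alone Adam9 was at -0.08 for ADAM9i minus WT and -0.05 for Rosa26-KO minus WT, both reversed. With Rosa26-KO vehicle as the control, WT values reversed for Cnn1 (-0.29), Myl9 (-0.25), Il6 (0.98), Fdps (0.00), Acat2 (-0.33), Atf3 (0.45) and Adam12 (-2.25). With ADAM9i vehicle they reversed for Cnn1 (-1.61), Myl9 (-0.43), Mmp9 (-0.04), Slc7a11 (0.28), Fdps (-0.06), Acat2 (-0.36), Col3a1 (-0.10), Atf3 (1.01) and Adam12 (-2.55). Among these, Mmp9, Fdps and Col3a1 missed the threshold. Against Rosa26-KO in place of WT, Cxcl1 reversed to 0.22 for the difference of responses, and under vehicle Pdgfra to -0.01 and Fos to 1.64. With Rosa26-KO vehicle as the control of both responses that control cancels, which leaves the direct difference of the treated groups. Its sign was opposite to the difference of responses for Fdps (0.40), Col3a1 (0.68) and Adam9 (-0.04), but it tests no difference of responses. Ccl2 in Adam9-KO was at 0.00 with RLE and DESeq2 and at -0.01 with library size alone. The cause was not tested.

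Over the 594 called entries that the naming rule gave, 230 lost the call or reversed under at least 1 alternative, 75 of them by reversal. Rosa26-KO vehicle as the control changed 116 of 200 (55 reversed), ADAM9i vehicle 48 of 97 (22) and the Rosa26-KO response in place of the WT response 39 of 88 (13). The 200 include entries of Rosa26-KO minus WT, where that control cancels and the value is the direct difference of the treated groups. Leaving out 1 library changed 87, DESeq2 15, the replicate block 10, library size alone 5 and RLE 1, with 0 reversed.

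Leaving out 1 library gave 11348 to 11447 genes in WT, 397 to 638 in ADAM9i, 7555 to 7754 in Rosa26-KO, 0 to 3 in Adam9-KO, 10153 to 10364 for ADAM9i minus WT, 6367 to 6898 for Adam9-KO minus Rosa26-KO, 10247 to 10315 for ADAM9i against WT vehicle, 1760 to 2433 for Adam9-KO against Rosa26-KO vehicle, 10078 to 10198 for Rosa26-KO against WT vehicle and 8280 to 8435 for Rosa26-KO minus WT. The lowest were without ADAM9i treated replicate 3 (397) and without Adam9-KO vehicle replicate 1 (1760, and 1788 without replicate 2), and ADAM9i gave 423 without treated replicate 1 or vehicle replicate 3 and 453 without vehicle replicate 2. The 3 in Adam9-KO came without its treated replicate 1. Lists past the threshold numbered 8 to 10 (WT), 10 to 17 (ADAM9i), 9 to 10 (Rosa26-KO), 4 to 6 (Adam9-KO), 6 to 8 (ADAM9i minus WT), 10 to 10 (Adam9-KO minus Rosa26-KO), 12 to 12 (ADAM9i against WT vehicle) and 9 to 11 (Adam9-KO against Rosa26-KO vehicle), the 4 being without Adam9-KO vehicle replicate 1. r was 0.437 to 0.485 for WT and Rosa26-KO, -0.074 to -0.012 for WT and ADAM9i, -0.139 to -0.032 for Rosa26-KO and Adam9-KO and -0.067 to -0.01 for ADAM9i and Adam9-KO. Adam9 gave -0.03 to 0.08 in Adam9-KO, -0.19 to 0.01 for Rosa26-KO against WT vehicle and -0.05 to 0.16 for Rosa26-KO minus WT. Il6 gave -0.61 to 0.61 in Rosa26-KO and -0.35 to 0.01 in Adam9-KO, Myh11 -0.25 to 0.94 and Ccl2 -0.07 to 0.05 in Adam9-KO. Depth limits these values least for abundant genes, and Il6, Myh11 and Cnn1 are near the level at which a few counts decide the change.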

Other observations

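All comparisons in this part were chosen after the data were seen, and no explanation was tested for them. The rhCTHRC1-treated groups were compared directly. ADAM9i and WT cells differed in 10179 genes (5273 higher and 4906 lower in ADAM9i), Adam9-KO and Rosa26-KO cells in 7548 (3907 higher and 3641 lower in Adam9-KO), and Rosa26-KO and WT cells in 6448 (3641 higher and 2807 lower in Rosa26-KO). Interferon-response genes were lower in 34 of 35, 32 of 35 and 32 of 35. Unfolded protein and ATF4 genes were higher and lower in 17 and 10, 28 and 0, and 10 and 16. Acta2 was higher by 2.99 in ADAM9i than in WT and by 3.22 in Adam9-KO than in Rosa26-KO cells, and differed by -0.26 between Rosa26-KO and WT cells (adjusted p = 0.0625). Egr1 differed by -3.17, 1.66 and -5.44 in the same order, Irf7 by -3.01, -1.93 and -1.06, and Mmp2 by -0.84, -0.91 and 0.17.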
